A study of Mus musculus with 4 samples.

How the data were processed

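Total RNA from the livers of male B6SJL hybrid mice was hybridised to Affymetrix MG_U74Av2 arrays, with 1 array per sample and 4 arrays in all. The labels' titles and source names put 2 arrays in the wild-type group and 2 in the PEPCK-TAg group. The authors deposited 1 intensity per probe set and array, a signal on a linear scale. Per the submitters' processing notes the deposited signals came from MAS5, whose version is not given in the sources used here. The 2% trimmed mean of the deposited signals over all probe sets, controls included, was 250.2 on each array, so the authors had scaled the arrays to 1 common level. Linear scaling sets equal means and not equal distributions, and the medians still differed between the arrays. Detection calls were not used here. Signals can saturate at the top and lose meaning near the background, and both shrink a fold change.

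Each array was scaled linearly to the mean of the 4 trimmed means, taken here without the controls, which changed signals by less than 0.2%. Signals were then raised to a floor at the 20th percentile of the pooled signals, 10.6, and log2 was taken. A probe set was tested if at least 2 of the 4 arrays, of either group, lay above the 40th percentile of the pooled signals, 41.3. This left 7877 probe sets of 5954 genes and set aside 4545 probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with no block and Benjamini-Hochberg adjustment over the probe sets tested. The standard errors are limma's moderated ones, with 6.60 degrees of freedom in all. A second count, with no test, took probe sets that differed by 2-fold or more and whose groups did not overlap, since an exact permutation test of 2 against 2 arrays cannot give a p under 0.333. Where an array of the lower group was at the floor, a fold is a bound and is given as at least that value. This holds for 122 of the called rises and 16 of the called falls, and list medians take such members at their bound. A group wholly at the floor has a spread of 0, so the SE and limma's p of such a gene hold none from that group.

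Probe sets were named from the platform's annotation table, which lists 1 gene symbol for 10833 of them, several for 396 and none for 1193. Of the 10833, 10817 matched a gene of the RefSeq table (assembly GRCm38.p6, used for names only), which changed 0 symbols. No gene is named from a probe set with several symbols. H19 and Trp53 had no probe set with a symbol of their own and have no value here. Of the 99 genes chosen by the rule given next, 20 had several probe sets tested, and in 10 of these the probe sets differed in sign or in their side of the threshold. These were Bgn, Cdkn1a, Col3a1, Mki67, Nap1l1, Nsdhl, Pck2, Pcx, Slc25a1 and Zap70. Affymetrix marks some probe sets as shared with related transcripts, among them those of Mup5, Cyp7b1, Cyp4a10, Cyp2d10, Zap70, Nqo1, Nop58 and Rpl10a, and their values can include relatives.

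The gene lists, the rule for the genes named and the alternatives were fixed before the data were examined, apart from those said to be chosen later. The genes named are the 12 largest rises and 12 largest falls among probe sets past the threshold with 1 symbol and no overlap between groups (predicted genes and clone names passed over). They also include up to 3 members with the smallest p in each list that passed the list test or held at least 3 called members, and Afp, H19, Igf2, Pck1, Trp53, Rb1, Cdkn1a, Mdm2, Ccnd1, Alb, Cyp7a1 and G6pc. Xist and Ddx3y served as a check of sex. In some lists called members outside the rule were also named, after their values were seen. In the other lists such members are given by their count only. The 36 lists covered the cell cycle, p53 targets, apoptosis, oncofetal genes, hepatocyte functions and zones, lipid, glucose and amino acid metabolism, male- and female-biased genes, stress and interferon responses, ribosomes, the respiratory chain, the clock, signalling and markers of other cell types. Each list was tested with camera at a preset inter-gene correlation of 0.01, on the brightest probe set of each gene, with adjustment over the 36 lists, all of which had at least 5 genes tested. Camera with an estimated correlation and fry were alternatives. The count of members adjusted over the list alone used Benjamini-Hochberg within the list.

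The alternatives were quantile normalization, the deposited values without scaling, floors at the 10th and 40th percentiles, a pseudocount at the 20th percentile in place of the floor, no filter, a filter at the 60th percentile, each array left out in turn, the replicate number as a block, eBayes without a trend or with a robust fit, an adjusted p of 0.1, an adjusted p of 0.05 with a 2-fold change, the fluidics station as a block, and the mean over the probe sets of a gene in the lists. Scanner type as a block, and the station as a block for lists and single genes, were chosen after seeing the data. The arrays were scanned on 3 days: wild-type 1 and PEPCK-TAg 1 on scan day 1, wild-type 2 alone on scan day 2 and on a second type of scanner, and PEPCK-TAg 2 alone on scan day 3 and from a second fluidics station. Scan day as a block leaves no residual degrees of freedom, so values within the pair of scan day 1 are given in its place. Both PEPCK-TAg arrays came from 1 chip lot and the wild-type arrays from a lot each, and lot and group cannot be told apart.

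The functions were tested on simulated data: 20 sets of 4 arrays with the real mean levels and limma's fitted noise, in which 200 probe sets were changed and a list was shifted 2-fold. In this comparison of 2 arrays against 2, with a median of 7654 probe sets tested, 1.05% of the probe sets changed 2-fold, 44.5% of those changed 4-fold and 74.8% of those changed 8-fold were recovered, and 4.89% of the calls fell on unchanged probe sets. Camera with the preset correlation called the shifted list in 20 of 20 sets and 0 of 700 tests of unshifted lists, and with an estimated correlation it called the shifted list in 0 of 20. The simulated genes were independent, which real genes are not. Far fewer probe sets were changed than the 985 called in the real data. Benjamini-Hochberg adjustment is stricter when fewer change, so these recovery rates may be too low for the real data.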

Results

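Gene expression was measured in total liver RNA of male mice of a B6SJL hybrid strain, aged 50 to 66 days, on Affymetrix MG_U74Av2 arrays. The mice had eaten a diet rich in protein (65% protein and 10% carbohydrate) for 4 weeks from weaning. The PEPCK-TAg mice carry a transgene that makes the large T and small t proteins of the SV40 virus in the liver. Large T binds the RB family of pocket proteins and p53, and small t binds the phosphatase PP2A. The wild-type mice carry no transgene. Each group had 2 arrays, and the series calls them duplicate measurements. The sources used here do not say that the arrays of a group came from separate animals, so each p-value measures the spread between these arrays only, which may be technical. The value table holds 12488 probe sets, of which 66 are array controls. The median signal was 68.4 and 66.6 on the wild-type arrays and 77.0 and 84.7 on the PEPCK-TAg arrays. Of the 12422 probe sets that are not controls, 58.9% and 58.1% lay above the filter level of 41.3 on the wild-type arrays, and 60.2% and 62.8% on the PEPCK-TAg arrays. The ratio of the 3' to the 5' control probe sets, a sign of RNA quality, was 4.33 and 3.41 for actin on the wild-type arrays and 3.82 and 3.14 on the PEPCK-TAg arrays, and 5.35 and 3.80 against 4.57 and 2.90 for Gapdh. The number of arrays limits the precision of every value.

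The comparison asks how prolonged exposure to the viral oncoproteins altered liver gene expression. Of the genes tested, 38 of 43 mitosis genes, 9 of 15 oncofetal genes, 13 of 33 myeloid markers and 8 of 14 erythroid genes rose in PEPCK-TAg liver, and 7 of 10 male-biased liver genes and 9 of 33 genes of amino acid catabolism and the urea cycle fell. Camera with a preset correlation called all 6 of these lists, and none passed with an estimated correlation (lowest adjusted p 0.217). That setting called a list shifted 2-fold in 0 of 20 simulated sets, so a list's failure under it says little. In limma's moderated test, 985 of the 7877 probe sets tested passed a Benjamini-Hochberg adjusted p of 0.05, 717 of them higher in PEPCK-TAg liver and 268 lower. The calls covered 567 genes that rose and 196 that fell. The rises were also larger: 370 probe sets rose at least 4-fold and 78 fell by as much, and 62 against 2 passed 16-fold. Without a test, 1616 probe sets differed by 2-fold or more with no overlap between the groups, 1154 higher and 462 lower (888 higher and 695 lower under quantile normalization). The groups did not overlap in 59.8% of the probe sets tested, where chance gives 33.3% if the arrays are exchangeable. Chip lot and group cannot be told apart, so a lot difference could also raise this share. The median log2 difference of all probe sets tested was 0.051. Pearson's r across the probe sets tested was 0.943 between the wild-type arrays, 0.953 between the PEPCK-TAg arrays and 0.812 to 0.844 between groups, and probe sets are not independent replicates. With an array left out and the filter applied anew, the number of calls was 1689 without wild-type 1, 1179 without wild-type 2, 167 without PEPCK-TAg 1 and 127 without PEPCK-TAg 2. The filter then left 33, 37, 237 and 230 of the 985 probe sets untested. It was 165 with no filter on dim probe sets and, with the fluidics station as a block, 0, where 1432 passed an unadjusted p of 0.05.

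Among genes with a symbol of their own, clone names passed over, the largest rise over the floor of 10.6 was that of a probe set of Mki67, a marker of cycling cells. A probe set of the transcript D17H6S56E-5 rose by more (log2 difference 7.31 ± 0.27 SE). Mki67 was at the floor on both wild-type arrays and at a signal of 1374 and 1324 on the PEPCK-TAg arrays, at least 127-fold higher (log2 difference 6.99 ± 0.28 SE, limma adjusted p = 0.000319, n = 2 arrays per group, as for every value here). The floor left the wild-type arrays of this probe set with a spread of 0. A further Mki67 probe set did not share the rise (log2 difference -0.65 ± 0.46 SE, adjusted p = 0.386). With a floor at the 40th percentile Mki67 gave 5.03, below Igf2 at 6.45. Sult2a2, a sulfotransferase of steroids and bile acids, rose at least 124-fold, and S100a9 and S100a8, the subunits of the granulocyte protein calprotectin, rose at least 115-fold and 48.4-fold. Igf2, a fetal growth factor, rose 87.4-fold, from signals of 42.8 and 138.8 to 6045 and 7512.7 (log2 difference 5.60 without wild-type 1 and 7.30 without wild-type 2). A further Igf2 probe set stayed between 2.1 and 4.6 on all 4 arrays, below the filter level. Ngp, a granule protein of neutrophils, rose 83.9-fold, Cdk1, the kinase that drives mitosis, 59.3-fold, and Rgs2, a regulator of G protein signalling, 59.2-fold. These sizes depend on the floor, and Cdk1 read 11.7 and 13.5 on the wild-type arrays, close to it. With a floor at the 40th percentile the log2 differences of Ngp, Cdk1 and Rgs2 were 5.31, 4.18 and 4.74, against 6.39, 5.89 and 5.89. Hemgn of erythroid precursors rose at least 45.6-fold, and the peroxisomal oxidase Hao2 at least 43.7-fold. Top2a, a topoisomerase of dividing cells, rose at least 42.2-fold and Rrm2, a subunit of ribonucleotide reductase, 39.4-fold. The largest fall in all 4 arrays was that of Hsd3b5, a steroid dehydrogenase of male liver, at 31.1-fold (log2 difference -4.96 ± 0.58 SE, adjusted p = 0.00392). Cyp1a2, a cytochrome P450 of pericentral hepatocytes, fell 26.0-fold (-4.70 ± 0.22 SE, adjusted p = 0.000449). The order of this pair rests on wild-type 1: without it Cyp1a2 gave -4.80 and Hsd3b5 a fall smaller by 0.80, and without wild-type 2 Hsd3b5 gave -5.92. Cyp7b1 fell 15.2-fold, the histone gene H3c14 12.8-fold, Zap70 12.7-fold, Cyp4a12b 12.6-fold and the serum amyloid gene Saa4 11.3-fold. The growth factor receptor Egfr fell 8.74-fold, Dct 8.66-fold, the ornithine aminotransferase Oat 8.61-fold, and Lama3 and Elovl3 at least 8.22-fold and 8.21-fold. Dct read 11.3 and 17.4 on the PEPCK-TAg arrays, near the floor. Its log2 difference was -3.11, and -1.55 with a floor at the 40th percentile. Lama3, at -3.04 on the log2 scale, gave -2.44 without wild-type 1 and -3.63 without wild-type 2. A further Zap70 probe set did not pass (log2 difference -0.84, adjusted p = 0.161).

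**Figure D1:**
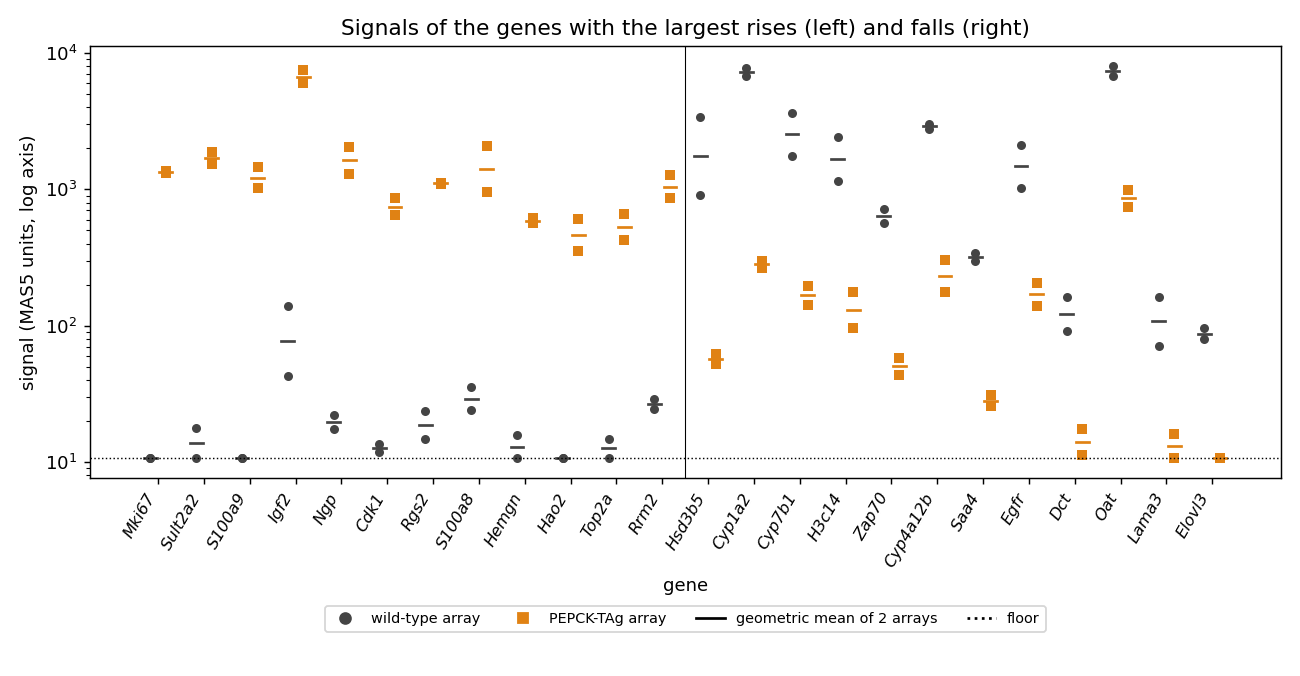
Signal (MAS5 units, log axis) of the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per array (2 wild-type and 2 PEPCK-TAg arrays per gene), a line at each group's geometric mean and a dotted line at the floor of 10.6. Mki67 lies at the floor on both wild-type arrays and at 1374 and 1324 on the PEPCK-TAg arrays, and no gene shown has overlapping groups.

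Genes of cell division rose together. Of 43 mitosis genes tested, 38 rose and none fell (42 rose adjusted over the list alone), with a median log2 difference of 3.15, or 8.90-fold (2.45 without PEPCK-TAg 1). With an array left out the filter was applied anew, and genes dim in wild-type liver, such as Mki67, went untested. Only 17 of the 43 lay above the filter level on both wild-type arrays, so 2.45 is not over the same genes. Over the 43, PEPCK-TAg 2 minus PEPCK-TAg 1 had a median of -0.19. Camera with a preset correlation of 0.01 gave the list an adjusted p of 4.18e-26, and the adjusted p was 0.217 with an estimated correlation. Besides Mki67 and Cdk1, Stmn1, a regulator of microtubules, rose 20.4-fold (log2 difference 4.35 ± 0.25 SE). Of 42 genes of DNA replication and S phase, 35 rose (38 adjusted over the list alone), with a median of 2.41 and an adjusted p of 2.27e-20 by camera, 0.217 with an estimated correlation. The helicase subunits Mcm5 and Mcm4 rose 19.3-fold and 23.5-fold (4.27 ± 0.24 SE and 4.55 ± 0.29 SE). Of 16 G1 cyclins, CDK inhibitors, pocket proteins and E2F factors, 9 rose (11 adjusted over the list alone), with a median of 1.60 and an adjusted p of 0.000158, which was 0.222 with an estimated correlation. The median was 0.98 without PEPCK-TAg 2 and 0.90 with no filter, settings that change which members are tested. The members that moved were not all drivers of the cycle: Rbl1, a pocket protein (p107), rose 9.90-fold, and the CDK inhibitors Cdkn1c and Cdkn2c rose 9.65-fold and 7.36-fold. Rb1 rose by 1.58 ± 0.34 (SE) on the log2 scale (adjusted p = 0.0306), whereas cyclin D1 (Ccnd1) gave -0.60 ± 0.29 SE (adjusted p = 0.222). In the pair of arrays scanned on 1 day (wild-type 1 and PEPCK-TAg 1), the medians of these 3 lists were 2.95, 2.61 and 1.65. Beside these rises, some markers of myeloid and erythroid cells, whose precursors divide, also rose (13 of 33 and 8 of 14).

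The list of p53 targets did not pass. Of 15 p53 targets tested, 2 rose and none fell (2 adjusted over the list alone), with a median of 0.28 and a camera adjusted p of 0.179. Cdkn1a, the CDK inhibitor p21, rose by 2.32 ± 0.43 (SE) on the log2 scale (adjusted p = 0.0186), and a further probe set of it gave 1.07 (adjusted p = 0.324). Apaf1 of the apoptosome rose by 3.21 on the log2 scale (adjusted p = 0.0130), or 3.94 without wild-type 1 and 2.48 without wild-type 2. Mdm2, the ubiquitin ligase of p53, gave 0.041 ± 0.25 SE (adjusted p = 0.931), a sign that turned under quantile normalization. Of 24 apoptosis genes, 2 rose (2 adjusted over the list alone), Bcl2l11 and Apaf1, with a median of 0.17 and an adjusted p of 0.508.

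Of 15 oncofetal genes tested, known from fetal liver and liver tumours, 9 rose and none fell (10 higher and 1 lower adjusted over the list alone), with a median of 3.10 in all 4 arrays, 2.97 in the pair of 1 scan day and 1.54 with no filter. The list's camera adjusted p was 0.000227, and 0.393 with an estimated correlation. Besides Igf2, the surface protein Cd24a rose 34.9-fold (5.12 ± 0.28 SE), lipoprotein lipase (Lpl) 26.9-fold (4.75 ± 0.23 SE) and the glypican Gpc3 23.0-fold (4.52 ± 0.27 SE). Afp, the fetal serum protein alpha-fetoprotein, did not follow: its probe set gave -0.42 ± 0.35 SE (adjusted p = 0.464), with signals of 58.8 and 73.0 in wild-type and 45.8 and 52.3 in PEPCK-TAg liver. Of 16 biliary and progenitor epithelium markers, 5 rose (6 adjusted over the list alone), with a median of 0.62 and a camera adjusted p of 0.193. They were Anxa2 (1.46 ± 0.25 SE), Krt18 (1.08 ± 0.23 SE), Cldn7 (at least 5.57-fold), Notch2 and Ddr1. Krt18 already read 1228.7 and 1254.2 on the wild-type arrays, so its rise need not come from biliary or progenitor cells.

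Of 33 markers of Kupffer and other myeloid cells, 13 rose and none fell (18 adjusted over the list alone), with a median of 1.35 and a camera adjusted p of 2.84e-07, which was 0.217 with an estimated correlation. Mpo, the myeloperoxidase of granulocytes and their precursors, rose at least 30.4-fold (log2 difference 4.93, with 5.56 without PEPCK-TAg 1 and 4.29 without PEPCK-TAg 2), the lectin Lgals3 at least 18.1-fold and the adaptor Tyrobp 4.41-fold. Of 14 genes of erythroid cells and blood, 8 rose (10 adjusted over the list alone), with a median of 1.65 and an adjusted p of 5.56e-05, which was 0.458 with an estimated correlation. Carbonic anhydrase 2 (Car2) rose 25.7-fold, the membrane protein Epb42 at least 11.6-fold and the globin gene Hbb-b2 5.03-fold. The same-day medians of the myeloid and erythroid lists were 1.02 and 1.44. Of 32 acute phase genes, 7 rose and 3 fell (7 and 5 adjusted over the list alone). Their median was -0.056 while camera put the list on the higher side, with an adjusted p of 0.899. S100a8 and S100a9 of granulocytes were among the rises, and Saa4, Orm1 and Serpina3n were the falls. Of 11 lymphocyte markers, 2 rose (2 adjusted over the list alone), Ccl5 and Ltb, with a median of -0.060 and an adjusted p of 0.651. Endothelial markers showed 1 rise among 21 (Icam2, and 0 adjusted over the list alone), with a median of 0.29 and an adjusted p of 0.508. Stellate cell, fibroblast and matrix genes showed 2 rises and 1 fall among 25 (the same numbers adjusted over the list alone). Lgals1 rose 3.29-fold, Col3a1 rose 2.33-fold and Bgn fell 3.17-fold, the latter pair each with a further probe set that did not pass. That list's median was 0.12 while camera put it on the lower side (adjusted p = 0.508).

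**Figure D2:**
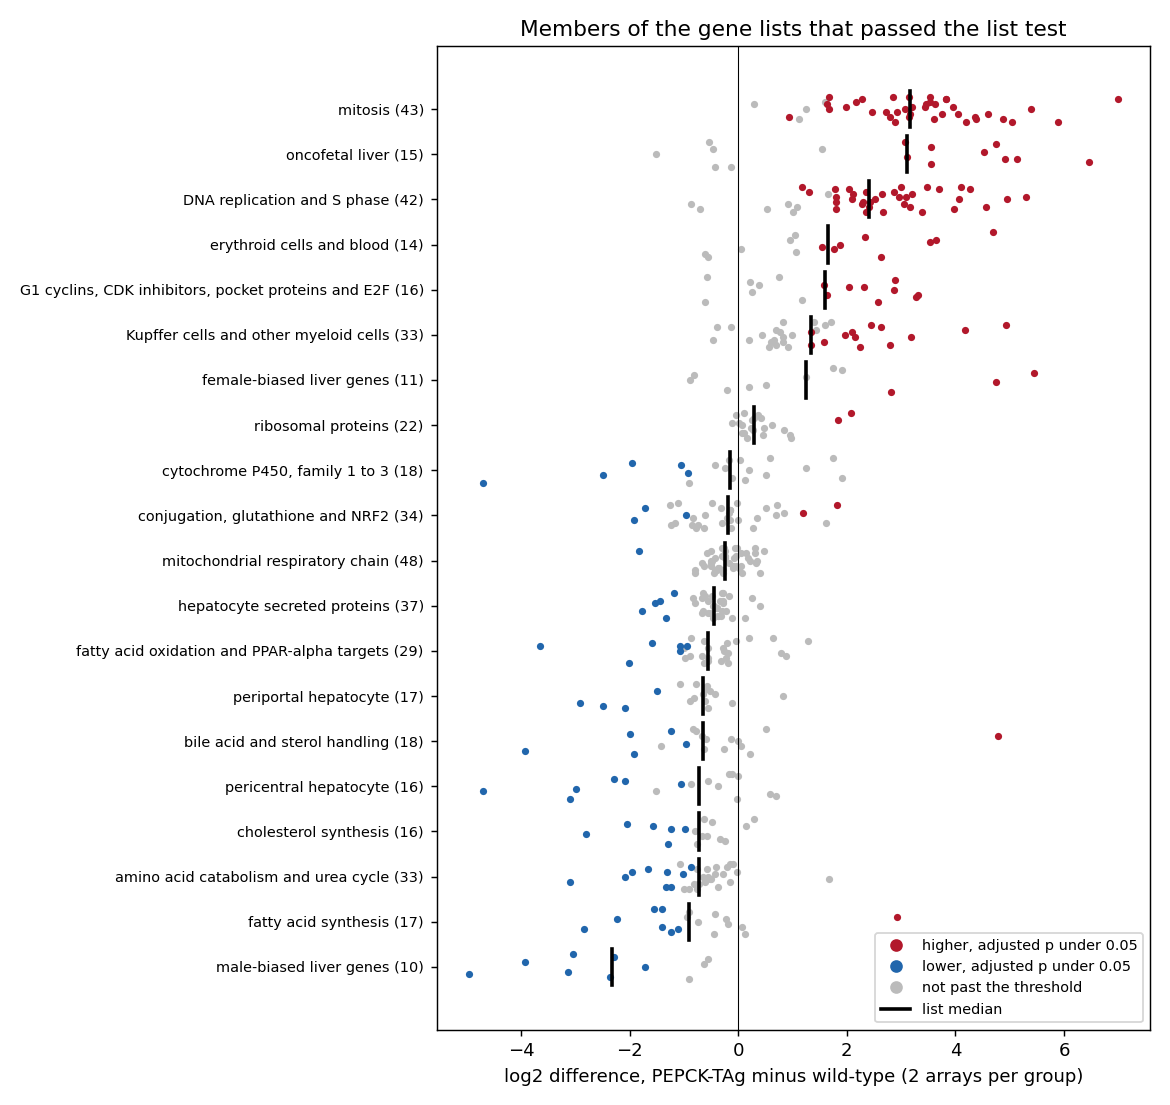
Log2 difference (PEPCK-TAg minus wild-type, 2 arrays per group) of each tested member of the 20 gene lists that passed the camera test with a preset correlation, with 1 point per gene, the number of genes tested in parentheses and a black bar at the list median. Red and blue points passed an adjusted p of 0.05 over all probe sets, and the medians run from -2.32 for male-biased liver genes to 3.15 for mitosis.

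Of 10 male-biased liver genes tested, 7 fell and none rose (8 adjusted over the list alone), with a median of -2.32, or 4.99-fold, and a camera adjusted p of 4.82e-08, which was 0.290 with an estimated correlation. The median was -1.71 without wild-type 1. Hsd3b5 and Cyp7b1 are named above, and the major urinary protein gene Mup5 fell 5.14-fold (-2.36 ± 0.28 SE). Its near-identical relatives may share its probes. Of 11 female-biased genes, 3 rose (4 adjusted over the list alone), Hao2, Lpl and Abcd2, the last at least 7.03-fold. That list had a median of 1.25 and an adjusted p of 0.0446, which was 0.466 with an estimated correlation. Its call was lost without wild-type 1, where the median was 0.082, and without either PEPCK-TAg array, with medians of 0.80 without PEPCK-TAg 1 and 0.20 without PEPCK-TAg 2. Without wild-type 2 the median was 2.59, with scanner type as a block 2.62 (2 settings that kept the call), and with a floor at the 40th percentile or a filter at the 60th, which ended it, 0.65 and 0.35. Without either PEPCK-TAg array the filter left Hao2 and Abcd2 untested, so the medians without those arrays leave these rises out. The labels give male mice, and Xist, the transcript of the inactive X chromosome, read 16.7 and 3.7 on the wild-type arrays and 8.3 and 12.3 on the PEPCK-TAg arrays, all below the filter level. Ddx3y had no probe set with a gene symbol of its own.

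Of 33 genes of amino acid catabolism and the urea cycle, which a diet rich in protein engages, 9 fell and none rose (10 adjusted over the list alone), with a median of -0.73 and a camera adjusted p of 2.17e-09, which was 0.217 with an estimated correlation. Besides Oat, the glyoxylate aminotransferase Agxt fell 3.87-fold and tryptophan dioxygenase (Tdo2) 3.17-fold. Of 16 pericentral hepatocyte markers, 6 fell (7 lower and 1 higher adjusted over the list alone), with a median of -0.71 and an adjusted p of 4.46e-05, which was 0.217 with an estimated correlation. Rgn fell 4.25-fold beside Cyp1a2 and Oat. Of 17 periportal markers, 4 fell (5 lower and 1 higher adjusted over the list alone), with a median of -0.65 and an adjusted p of 2.51e-06, which was 0.217 with an estimated correlation. They included Cyp2f2 at 5.65-fold, Sult5a1 at 7.55-fold and histidine ammonia lyase (Hal) at 4.27-fold. Of the 17, 14 also stand in another list. This also holds for 7 of the 16 pericentral markers, 11 of the 18 cytochrome P450 genes below and 7 of the 11 female-biased genes. These lists are therefore not separate findings. Of 18 cytochrome P450 genes of families 1 to 3, 5 fell (6 lower and 1 higher adjusted over the list alone), among them Cyp2d10 at 3.89-fold. Their median was -0.15 and the adjusted p 0.0231, which was 0.529 with an estimated correlation, and the call was lost under quantile normalization, without wild-type 2 and without PEPCK-TAg 1. Of 37 secreted hepatocyte proteins, 5 fell (5 adjusted over the list alone), among them Ttr at 3.40-fold, Mbl2 at 2.88-fold and Itih1 at 2.50-fold. Their median was -0.44 and the adjusted p 5.77e-07, which was 0.447 with an estimated correlation, but the median was 0.0018 and the call was lost under quantile normalization. Albumin (Alb) gave -0.56 ± 0.25 SE (adjusted p = 0.192) and 0.036 under quantile normalization. Among 20 hepatocyte transcription factors, Nr1i3 fell by 1.55 on the log2 scale (0 fell adjusted over the list alone), with a median of -0.095 and an adjusted p of 0.193.

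Pck1, the gene of the enzyme for which the transgene is named, gave -0.89 ± 0.33 SE (adjusted p = 0.127). G6pc, which releases free glucose, gave -0.82 ± 0.21 SE (adjusted p = 0.0519). Of 18 genes of gluconeogenesis and glycogen, 2 rose and 2 fell (3 and 4 adjusted over the list alone). The mitochondrial Pck2 rose 5.02-fold and the pyruvate kinase gene Pkm by 1.03 on the log2 scale, and pyruvate carboxylase (Pcx) fell 2.33-fold and Ugp2 1.92-fold. The list's median was 0.023 while camera put it on the lower side (adjusted p = 0.508).

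Of 16 cholesterol synthesis genes, 6 fell and none rose (7 adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 4.46e-05, which was 0.301 with an estimated correlation. Mvd fell at least 6.98-fold, Msmo1 4.12-fold and Nsdhl 2.98-fold. Of 17 fatty acid synthesis genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.91 and an adjusted p of 4.46e-05, which was 0.217 with an estimated correlation. Elovl5 fell 2.94-fold and the citrate carrier Slc25a1 2.63-fold. The member that rose was Pparg, a nuclear receptor of fat storage, at least 7.56-fold higher (log2 difference 2.92, with 3.61 without wild-type 1 and 2.22 without wild-type 2). Of 29 genes of fatty acid oxidation and PPAR-alpha targets, 6 fell (6 adjusted over the list alone), with a median of -0.56 and an adjusted p of 0.000227, which was 0.439 with an estimated correlation. The call was lost under quantile normalization, where the median was -0.32. Besides Cyp4a12b, Cyp4a10 fell 4.03-fold and Cpt2 3.01-fold. Of 18 genes of bile acid and sterol handling, 5 fell and 1 rose (8 and 1 adjusted over the list alone), with a median of -0.65 and an adjusted p of 0.000415, which was 0.222 with an estimated correlation. Hsd3b7 fell 3.79-fold beside Cyp7b1, both of them enzymes of bile acid synthesis, and the transporter Abcb1a rose at least 27.5-fold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave -0.010 ± 0.52 SE (adjusted p = 0.992). Without wild-type 1 it gave 0.67, and without wild-type 2 -0.69.

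Of 48 respiratory chain genes tested, 1 fell (1 adjusted over the list alone), Sdha at 3.56-fold, and Sdhc and Uqcrc1 gave -0.79 each (adjusted p = 0.0886 and 0.0901). The list's median was -0.25 and its camera adjusted p 0.00263, which was 0.466 with an estimated correlation. Its call was lost under quantile normalization and without PEPCK-TAg 1. Of 34 genes of conjugation, glutathione and NRF2, 2 rose and 3 fell (3 and 9 adjusted over the list alone), with a median of -0.19 and an adjusted p of 0.0171, which was 0.474 with an estimated correlation. Aox1 fell 3.78-fold, Gstm6 3.30-fold and Ephx1 by 0.95 on the log2 scale, and Nqo1 and Cbr1 rose, Nqo1 3.54-fold. That call was lost under quantile normalization, without wild-type 2 and without PEPCK-TAg 1. Of 22 ribosomal protein genes, 2 rose (2 adjusted over the list alone), Rps19 at 4.21-fold and Rpl13a at 3.57-fold, and Rpl10a gave 0.97 (adjusted p = 0.0589). Their median was 0.28 and the adjusted p 0.0398, which was 0.534 with an estimated correlation, and the call was lost without either wild-type array and without PEPCK-TAg 2. Of 35 genes of ribosome biogenesis and MYC targets, 4 rose (8 adjusted over the list alone), with a median of 0.39 and an adjusted p of 0.166. Nop58, Nap1l1 and Nop56 rose 5.05-fold, 4.80-fold and 3.93-fold, and Npm1 by 0.95 on the log2 scale.

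The other lists did not pass the list test. Of 28 Wnt and growth factor genes, 2 rose and 3 fell (the same numbers adjusted over the list alone), with a median of -0.049 and an adjusted p of 0.193. Socs2 rose 4.51-fold and the phosphatase subunit Ppp2ca by 1.17 on the log2 scale. Egfr is named above, Igfals, which binds IGF1 in serum, fell 4.40-fold, and Igf1 fell (adjusted p = 0.0174). Of 34 interferon response genes, 4 rose and 1 fell (7 and 2 adjusted over the list alone), with a median of 0.35 and an adjusted p of 0.303. Rsad2 rose 2.75-fold and Irf8 2.53-fold, Trim30a and Gbp2 were the other rises, and H2-Q10 fell 1.94-fold. Without wild-type 1 that list was called higher with a median of 0.77, and without wild-type 2 the median was -0.047. Of 30 genes of the unfolded protein and amino acid responses, 2 rose and 2 fell (the same numbers adjusted over the list alone), with a median of -0.21 and an adjusted p of 0.0625. Ddit3 rose by 2.07 on the log2 scale and Psat1 3.49-fold, and Aars fell 2.50-fold and Sel1l by 1.05 on the log2 scale. That list was called lower without wild-type 1, with a median of -0.34, and without PEPCK-TAg 1, with a median of -0.43. Of 28 immediate early and heat shock genes, 2 rose (2 adjusted over the list alone), Klf6 and Myc, with a median of 0.25 and an adjusted p of 0.711. Of 15 circadian clock genes, 0 passed limma's test and 1 had an unadjusted p under 0.05 (0 adjusted over the list alone), with a median of -0.12 and an adjusted p of 0.241. Of 6 genes of pancreas and other adjacent tissue, 1 fell (1 adjusted over the list alone), Cela1, with a median of -0.41 and an adjusted p of 0.193. None of the 36 lists passed with an estimated correlation, where 8 had an unadjusted p under 0.05, and 13 passed with fry.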

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

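The alternatives were planned before the data were examined, apart from scanner type as a block, and the fluidics station as a block for lists and single genes. No called probe set changed sign under any setting that called it again. Of the 985 calls, 760 were shared with quantile normalization (846 calls), 779 with a floor at the 40th percentile (842) and 762 with scanner type as a block (977). Of the named genes, 89 were called and 0 of them changed sign, but none kept its call under every setting: the station block ended all 89 calls and no filter 70. Without PEPCK-TAg 1, 34 lost their call and 23 failed the filter and were not tested, without PEPCK-TAg 2 41 and 22, and the filter at the 60th percentile left 13 untested. Every other setting left at most 10 without a call, tested or not. Without a filter 165 probe sets were called (129 higher and 36 lower), 108 of them shared, from 12422 tested with 2.83 degrees of freedom against 6.60. The station block, which leaves PEPCK-TAg 2 to its own term and 3.04 degrees of freedom, called 0, 0 higher and 0 lower, with 1432 at an unadjusted p under 0.05. An adjusted p of 0.1 gave 1621 calls, 1108 higher and 513 lower. Without each array in turn the calls ranged from 127 to 1689 (88 to 1207 higher, 39 to 482 lower); 1 group then has 1 array, assumed to vary like the other group, and the lone array's spread is not measured. With the replicate block 1873 were called (1240 higher and 633 lower), including all 985. The numbers are not known to pair the samples: deviations of same-numbered arrays correlated at 0.253 across probe sets, with only 2 pairs. Quantile normalization moved the median of all probe sets tested by -0.14 (from 0.051 to -0.088) and gave 695 probe sets lower by 2-fold without overlap against 462, and 67.0% of its calls were higher against 72.8%. A filter at the 60th percentile left 1057 with a 2-fold change, 742 of them higher, since it tested 5381. Where no cause is named, the cause was not tested.

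Of the 20 lists that passed, 11 lost their call only with an estimated correlation (0 lists higher and 0 lower, against 8 and 12), a setting that also missed the 2-fold list in every simulated set. The other 9 lost it elsewhere too: female-biased genes under 9 further settings, ribosomal proteins under 7, and cytochrome P450 and conjugation genes under 5 each. Some lists whose estimated correlation lay below the preset 0.01 also lost their call with that setting. Among them were amino acid catabolism (-0.008), G1 genes (-0.024) and fatty acid synthesis (-0.052), so a higher correlation does not account for the loss in these lists. For amino acid catabolism camera's unadjusted p went from 1.8e-10 to 0.018. With 2 arrays per group this setting could hardly pass any list, so a loss under it does not count against a list. With the estimated correlation the adjusted p was 0.217 for the mitosis, DNA replication, amino acid, fatty acid synthesis, Kupffer, pericentral and periportal lists, 0.222 for G1 and bile acid genes, 0.29 for male-biased genes, 0.301 for cholesterol synthesis, 0.393 for oncofetal genes, 0.439 for fatty acid oxidation, 0.447 for secreted proteins, 0.458 for erythroid genes, 0.466 for female-biased and respiratory chain genes, 0.474 for conjugation genes, 0.529 for cytochrome P450 and 0.534 for ribosomal proteins. Quantile normalization left 7 lists lower and ended the calls of fatty acid oxidation (adjusted p = 0.0694), the respiratory chain (0.195), cytochrome P450 (0.295), and secreted proteins and conjugation genes (0.595 each). Fry left 6 lists lower; it ended the calls of erythroid genes (0.054), female-biased genes and cholesterol synthesis (0.0821 each), fatty acid oxidation (0.125), secreted proteins (0.137), cytochrome P450 (0.16), ribosomal proteins (0.165), the respiratory chain (0.213) and conjugation genes (0.321), and it called ribosome biogenesis (0.0134) and biliary genes (0.0485). The call of female-biased genes also ended with a floor at the 10th (0.0524) or 40th (0.0749) percentile, a filter at the 60th percentile (0.259), the replicate block (0.0611) and the station block (0.0918), and that of ribosomal proteins with no filter (0.0828), the station block (0.265) and the mean over probe sets (0.0509). A filter at the 60th percentile called the unfolded protein list (0.02). Scanner type as a block ended the calls of cytochrome P450 (0.304) and conjugation genes (0.0502).

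The tests' direction turned only for lists and genes that had not passed. Under quantile normalization this held for Alb (0.036), Mdm2 (-0.10) and the gluconeogenesis list (median 0.13, adjusted p = 0.769); the median of the secreted proteins, not the test's direction, also crossed zero (0.0018). Lymphocyte markers turned with no filter (0.456) and with fry (0.137), which also turned the gluconeogenesis (0.455) and stellate lists (0.74). With scanner type as a block the endothelial median was -0.060 (adjusted p = 0.86) and the interferon median -0.043 (0.364). With arrays left out in turn, Mdm2 ranged from -0.11 to 0.19 and Cyp7a1 from -0.69 to 0.67. The filter was applied anew each time, so the list members tested can differ. The lists' adjusted p then ranged from 0.000485 to 0.213 for cytochrome P450 (medians -0.65 to 0.13), from 0.00149 to 0.151 for conjugation genes, from 3.65e-05 to 0.719 for female-biased genes, from 0.00049 to 0.211 for ribosomal proteins, from 0.000607 to 0.0599 for the respiratory chain and from 0.0164 to 0.227 for the unfolded protein list. For lists that turned it ranged from 0.00263 to 0.838 for the interferon list (medians -0.047 to 0.77), from 0.359 to 0.779 for endothelium (-0.060 to 0.34), from 0.213 to 0.963 for acute phase (-0.14 to 0.093), from 0.314 to 0.896 for stellate genes (-0.15 to 0.28) and from 0.18 to 0.845 for immediate early genes (0.020 to 0.54). Signal over background limits the dim genes: at a level near 10.6 a fold has no size, and 4545 probe sets were not tested. Of the 99 genes named by rule, 29 moved over 1.5-fold under at least 1 setting, 25 of them with a floor at the 40th percentile and 10 each with a floor at the 10th percentile or a pseudocount.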

Other observations

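All gene groups and tests in this part were chosen after the values were seen, and no group here was tested as a list. Of 14 tested genes of granulocytes and their precursors, 12 rose and 0 fell, with a median log2 difference of 4.27. Over all 17 on the array, with no filter, the median was 3.61. They included Camp (4.51), Ltf (4.34) and Lcn2 (4.50, with 3.88 without wild-type 1 and 5.12 without wild-type 2), proteins of neutrophil granules, and Myb (at least 4.19), a factor of blood cell precursors. Of the 14 genes, 5 also stand in lists of the report, and 3 lay above the filter level on both wild-type arrays. Of 13 genes of erythroid precursors, 9 rose, with a median of 2.62, 9 of the 13 stand in lists of the report, and 7 lay above the filter level in wild-type liver. The rises included Slc4a1 (3.64 ± 0.55 SE, with 4.43 without PEPCK-TAg 1 and 2.86 without PEPCK-TAg 2), Gfi1b (2.98) and Nfe2 (2.65). Gfi1b read 11.5 and 11.6 on the wild-type arrays, close to the floor, so the size of its rise depends on the floor. Alas2 gave -0.57 and Tfrc 0.042, neither past the threshold. Of 11 imprinted genes tested, 4 rose (Igf2, Peg3 by 3.55, Cdkn1c by 3.27 and Sgce by 2.92), 1 fell (Slc22a18, -1.17), and the others, such as Dlk1 (-0.55) and Gnas (-0.22), did not pass.

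Of 11 genes tested of glucose and energy metabolism whose products are typical of muscle, brain or fetal tissue, 4 rose and 7 did not pass: Pfkp at least by 4.99 on the log2 scale, the adenine nucleotide carrier Slc25a4 by 4.45, the brain glycogen phosphorylase Pygb by 4.23 and Pkm by 1.03. Of 3 genes tested for the forms in liver, 0 passed limma's test (Slc2a2 0.46, Pfkl 0.46, Pklr -1.17). The probe set of the transcript D17H6S56E-5 went from signals of 20.5 and 22.7 in wild-type to 3002.8 and 3892.9 in PEPCK-TAg liver, and a further probe set stayed at 7.4 or below on all 4 arrays. The wild-type arrays differed from each other in some sex-biased genes. Cyp2b9 read 34.9 and 2147.3, Cyp4a14 269.5 and 3557.9, Cyp17a1 238.1 and 954.3, and Hsd3b5 3422.5 and 902.8. The first 3 stand in the female-biased list and were higher on wild-type 2, and Hsd3b5 stands in the male-biased list and was higher on wild-type 1. Cyp4a14 also stands in the list of fatty acid oxidation and PPAR-alpha targets, and Cyp2b9 in that of cytochrome P450 genes. Their differences between the wild-type arrays therefore need not follow sex bias. Not all members differed: female-biased Lpl read 82.4 and 81.8, and male-biased Mup5 10784.1 and 10269.6.

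Of the 14 granulocyte genes tested, 12 rose, but the filter keeps dim genes that rose, so the tests used all 17 on the array. More blood of unchanged make-up left in the tissue would raise them no more than globin, and this stays open: 12 of the 17 lay above the globin gene that rose most, Hbb-b2 (2.33), but their lower quartile, 1.78, differed from it by -0.55. A difference between scan days, stations or scanner types would leave little in the pair that shared all of these, where the median of the 17 was 2.77 and the lower quartile 1.73. A rise of granulocytes in the blood, blood cell formation in the liver and an effect of chip lot stay open as hypotheses, untested.

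Of 10 male-biased genes, 7 fell, and some sex-biased genes also differed between the wild-type arrays, as given above. A lower share of hepatocyte RNA would lower other hepatocyte transcripts alike, but the male-biased median minus the secreted median was -1.88, with an upper quartile of -1.10 against a lower quartile of -0.66 for the secreted proteins and a median of -0.095 for hepatocyte transcription factors. Female RNA through a mislabelled sample is not excluded: the highest Xist signal on a PEPCK-TAg array was 12.3, but 0 arrays are labelled female, so nothing shows that the probe set responds. Of the Y-linked genes, Eif2s3y read 294.1 and 227.6 in wild-type and 403.6 and 405 in PEPCK-TAg liver, which argues against it, but its probe set is of a kind that related sequences share and may also read the X-linked relative, Uty lay near the filter level (52.4 and 70.9 against 50.6 and 36.2), Kdm5d was dim on all arrays (3.2 and 8.2 against 9.4 and 16.9), and a Sry probe set below the filter level read less in PEPCK-TAg liver (34.6 and 35.1 against 4.3 and 10.3). A change in the hormonal control of these genes may be a biological explanation, and it was not tested.

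Of 43 mitosis genes, 38 rose. The choice of scaling changed this little: the mitosis median, less the median of all probe sets, was 3.11 under quantile normalization and 3.10 with linear scaling or none. The subtraction cancels any shift shared by all probe sets, so this value cannot test such a shift. The median of all probe sets tested was itself 0.051 with linear scaling. Cycling precursors of blood cells, in place of liver cells, may contribute, and this cannot be told apart from dividing hepatocytes here. Between the PEPCK-TAg arrays (array 2 minus array 1) the mitosis genes moved by a median of -0.19, while the granulocyte genes moved by 0.70 and the erythroid precursor genes by 0.42. Precursors in a fixed ratio to the mature cells would have moved the mitosis genes with them, but it is not known that the ratio was fixed. The precursor genes did not move alike: Myb (0.22), Klf1 (0.052) and Hemgn (-0.12) moved little. Signals rose from array 1 to array 2 for Mpo (207.8 and 498.1), Prtn3 (109.4 and 239.4) and Elane (90.4 and 225.1). Whether the stages of these cells differ between the arrays cannot be told from these values.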
